A study of Mus musculus with 10 samples.

How the data were processed

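RNA was measured by sequencing in somatosensory cortex from mice of 2 conditional knockout (cKO) models of Nsd1, which encodes a histone H3 lysine 36 methyltransferase. The 2.5-month samples comprised 3 controls (Nex_Ctrl) and 3 Nsd1Nex-cKO samples (Nex_cKO). The 3-month samples comprised 2 controls (Camk2a_Ctrl) and 2 samples of the Camk2a model (Camk2a_cKO). Per the labels, total RNA was extracted with RNAiso Plus and made into libraries with an NEBNext Ultra II RNA kit. Nex_Ctrl replicates 1 and 2 and both Camk2a_Ctrl samples were labelled Nsd1fl/+, and Nex_Ctrl replicate 3 was labelled Nsd1fl/fl. The labels state no litter, day or batch, do not say whether the controls carried Cre, and do not say whether each replicate was a separate mouse. The submitters' processing notes name cutadapt, STAR, Cufflinks 2.2.1 and DESeq2, without role or order, and the genome builds mm10 and GRCm38.

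The authors deposited FPKM values (fragments per kilobase, scaled to the mapped fragments of each library) in 2 tables, one per model. The 2.5-month table had 29610 rows, of which 4463 carried no gene name and 1078 joined the names of several genes in one locus. The 3-month table had 54532 rows with Ensembl gene identifiers, positions, biotypes and the deposited gene length. In the 3-month table, FPKM multiplied by gene length was a whole multiple of one step per library for 100% of values within a tolerance of 0.1, and so reads per gene could be recovered. They summed to 17521841, 20074933, 16901717 and 16943855 reads in Camk2a_Ctrl replicates 1 and 2 and Camk2a_cKO replicates 1 and 2. The 2.5-month table allowed no such recovery, so the depth behind its values is unknown, and no interval or detection floor is given for them. Where a gene name occurred in several rows, the row of highest mean FPKM was kept (1864 rows left out of the 2.5-month table and 105 of the 3-month table), and unnamed rows were not tested. Of the single-gene names of the 2.5-month table, 21312 were found in the 3-month table as written and 562 through a RefSeq synonym, and 331 were not found. Positions are those of the 3-month table (GRCm38).

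Each table was fitted apart, because the tables were made with different gene models. Genes with FPKM of at least 1 in at least as many libraries as the smaller group were tested, 12528 in the Nex model and 12919 in the Camk2a model. Values were transformed to log2(FPKM + 1) and compared between cKO and control with limma 3.58.1 (lmFit, then eBayes with an intensity trend) in R 4.3.3. P-values are two-sided and were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. They measure the spread between samples. The pseudocount of 1 makes log2 changes of genes with low FPKM smaller than the ratio of their FPKM. "Higher", "lower", "rose" and "fell" stand for adjusted p under 0.05. The difference of the changes between models was tested with limma on the 10407 genes tested in both tables, as (Nex_cKO minus Nex_Ctrl) minus (Camk2a_cKO minus Camk2a_Ctrl), so that age, driver and table differ together between the 2 models. Overlap of calls was tested with Fisher's exact test, two-sided.

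Gene lists were fixed before the data were examined: 39 lists of markers of cortical layers, cell types and neighbouring regions, of pathways and of RNA quality. Those with at least 3 tested members (37 in the Nex model, 38 in the Camk2a model) were compared with all other genes by limma's camera with a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the lists. Alongside stand camera with an estimated correlation and fry, which asks whether the members move one way on balance without comparing them with other genes. With an estimated correlation, camera also judges its statistic by the few residual degrees of freedom of the fit, so that few lists can pass.

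Named genes followed a rule also fixed before the data were examined. In each model it took Nsd1, Neurod6 and Camk2a. It then took the 6 higher and 6 lower genes with the largest log2 change among those past the threshold, with groups that did not overlap and a mean FPKM of at least 1 in either group, leaving out Gm-number and Rik names and sex-linked genes. Of the first 8 lists by camera p that had a member past the threshold, it took up to 3 passing members. Where no gene of a model passed, it took the 4 genes of smallest p in each direction and 2 members of each of the first 8 lists, as values only. Of genes whose change differed between the models, it took the 4 with the largest difference in each direction. Other genes are said to have been chosen after their values were seen.

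Alternatives planned before the data were examined were a pseudocount of 0.1, no filter, a filter of FPKM 5, quantile normalization, rescaling by the median ratio, no intensity trend, robust variance moderation, a replicate block, and leaving out each library. Counts were to be fitted with another tool only if the files held counts, which they did not, and this was not run. Alternatives added after seeing the data were a correction for gene length (loess with a span of 0.5), limma voom on the recovered reads of the 3-month table, the Nex calls tested as sets in the Camk2a model, the gene lists under the further settings and without each library, and joint settings of the overlap. All 3 against 3 splits of the Nex libraries were fitted. The steps were tested on simulated data of the same size, with 200 changed genes and spreads drawn from the fitted prior. At a log2 change of 1, limma recovered 95% of changed genes in the Nex design, 83% in the Camk2a design and 86% in the test of differences, with 16, 5 and 8 calls among unchanged genes. In the simulation only genes above a bound of mean expression were changed, and genes varied independently. These rates therefore do not cover genes of low FPKM, smaller changes or a library that stands apart. The 200 genes had log2 changes of 1 or 2 in the same fit, and many true changes ease the Benjamini-Hochberg cutoff. Where few or no genes pass, as in the Camk2a model, the share recovered at a log2 change of 1 can be much lower. Values were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plotted with matplotlib 3.10.9.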

Results

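The series measured RNA in somatosensory cortex of mice in which Nsd1 was conditionally deleted. By its title, it asks whether histone methylation by NSD1 is needed to establish and to maintain neuronal identity. The Nex model deletes Nsd1 with Cre expressed from the Neurod6 (Nex) locus, in excitatory neurons from soon after they leave the cell cycle, and was sampled at 2.5 months with 3 control and 3 cKO libraries. The Camk2a model deletes it in excitatory neurons at a later age, and was sampled at 3 months with 2 control and 2 cKO libraries. Named genes and joined loci with FPKM of at least 1 numbered 12832 to 12902 in Nex_Ctrl libraries and 13154 to 13303 in Nex_cKO libraries. In the Camk2a model they numbered 12548 and 12651 in controls and 12761 and 12933 in cKO libraries. Read depth was unknown for the Nex libraries and was 16901717 to 20074933 recovered reads for the Camk2a libraries. Nex_cKO replicate 3 stood apart from the other Nex libraries. It had the Y-linked transcript Ddx3y at 16.2 FPKM and Xist, expressed from the inactive X chromosome, at 0.0035 FPKM. The other 5 Nex libraries had Ddx3y listed at 0 and Xist at 33.6 to 46.5 FPKM. Rows without a gene name held 41.55% of the summed FPKM of Nex_cKO replicate 3 and 2.33% to 19.4% in the other Nex libraries. All 4 Camk2a libraries had Ddx3y at 10.98 to 12.35 FPKM.

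The first comparison asks which transcripts differ in adult cortex when Nsd1 is deleted in postmitotic excitatory neurons. In Nex_cKO cortex, genes that were near 0 in control cortex appeared at clear levels, among them the developmental transcription factors Vax2, Barx1 and Twist1. Of 19 tested markers of layer 6 and subplate neurons 7 were lower, among them Syt6, Foxp2 and Grik3. The 560 higher genes had a median log2 change of 0.95 (interquartile range 0.63 to 1.38), and 252 of them (45%) had a control mean under FPKM 1. The 509 lower genes had a median of -0.45 (interquartile range -0.59 to -0.36), and 26 of them (5.1%) changed by more than 1 on the log2 scale, against 260 (46.4%) of the higher genes. Part of this contrast comes from genes near 0 in controls, which enter the test only through a rise. Among genes with a control mean of at least FPKM 1, a bound chosen after the data were seen, the 308 higher ones had a median of 0.74 and 84 (27.3%) changed by more than 1.

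These counts came from limma on 12528 genes and joined loci at Benjamini-Hochberg adjusted p under 0.05. At each of the 1069 called genes the 3 cKO values lay on one side of the 3 control values. Across all tested genes this held for 3803 (30.4%), where chance gives 10%. The number of lower genes was 160 without Nex_Ctrl replicate 1, 205 without Nex_Ctrl replicate 2, 161 without Nex_Ctrl replicate 3 and 219 without Nex_cKO replicate 1. Rescaling by the median ratio gave 618 higher and 298 lower genes, a higher share of 67.5% instead of 52.4%. The balance turned with a filter of FPKM 5 (197 higher, 347 lower) and without Nex_cKO replicate 2 (580 higher, 685 lower). Without Nex_cKO replicate 3, which stood apart, 635 genes were higher and 564 lower.

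Nsd1 itself was reported in the 2.5-month table only as a locus joined with its neighbour Prelid1, so that the level of Nsd1 alone could not be read. The joined locus had 129.9, 125.1 and 141.4 FPKM in the control libraries and 91.0, 118.1 and 105.6 FPKM in the cKO libraries, a log2 change of -0.34 (SE 0.10, adjusted p = 0.0863). Without Nex_cKO replicate 2 its log2 change was -0.43 (adjusted p = 0.0301). Neurod6 (chromosome 6, 55677822 to 55681263), the locus that carries the Nex-Cre insertion, fell from 31.6 ± 2.30 FPKM (SD, n = 3) to 18.0 ± 3.85 FPKM (SD, n = 3; log2 change -0.80, adjusted p = 0.00719). Camk2a, a kinase of excitatory synapses, had 726 ± 40.9 FPKM in controls and 662 ± 0.567 FPKM in cKO libraries (adjusted p = 0.459). The sign of its difference changed under quantile normalization (log2 change 0.0039).

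Among the named genes, the largest rise on the scale of log2(FPKM + 1) was that of Mgst2 (ENSMUSG00000074604, chromosome 3, 51660360 to 51682677), a microsomal glutathione transferase, from 0.227 ± 0.197 to 18.4 ± 1.56 FPKM (SD, n = 3 each; log2 change 3.99, SE 0.14, adjusted p = 1.33e-06). Parvg (ENSMUSG00000022439, chromosome 15, 84324026 to 84342978), a focal adhesion adaptor known from blood cells, rose from 1.70 ± 0.349 to 26.5 ± 0.896 FPKM (SD, n = 3 each; log2 change 3.36, SE 0.11, adjusted p = 1.07e-06). Mfap4, a microfibril-associated protein, rose from 0.671 to 14.1 FPKM, and Ccdc42 from 0.104 to 12.9 FPKM. Sec14l4 rose from 0.00886 to 9.32 FPKM, and the long noncoding RNA Lincenc1 from 0.0522 to 8.90 FPKM. The adjusted p of these 4 genes lay between 2.95e-06 and 1.17e-05. Each was higher in all 3 cKO libraries than in any control library.

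Among the lower genes, the neuropeptide precursor Cartpt (ENSMUSG00000021647, chromosome 13, 99898489 to 99901091) fell from 9.54 ± 3.24 to 2.76 ± 0.701 FPKM (SD, n = 3 each; log2 change -1.46, SE 0.21, adjusted p = 0.00333). The joined locus Nt5dc1/Tspyl4 fell from 6.93 to 1.34 FPKM (adjusted p = 0.000717). The haemoglobin loci, transcripts of red blood cells, were lower: Hba-a1/Hba-a2 fell from 100.5 to 31.9 FPKM (adjusted p = 0.014), Hbb-b1/Hbb-bs from 118.1 to 40.7 FPKM (adjusted p = 0.0239) and Hbb-b2 from 10.8 to 3.08 FPKM (adjusted p = 0.0114). How the fall divides among these similar genes is uncertain, since the table joins some of them and reads of such genes can map to several. The adjusted p of Hba-a1/Hba-a2 was 0.0671, 0.059 and 0.051 without Nex_Ctrl replicate 1, Nex_Ctrl replicate 3 and Nex_cKO replicate 1. That of Hbb-b1/Hbb-bs was 0.0942, 0.0938 and 0.0826 without the same libraries, and that of Hbb-b2 was 0.0526 without Nex_Ctrl replicate 3. Cacul1 fell from 4.21 to 0.797 FPKM (adjusted p = 0.0177), with 0.0607, 0.0751 and 0.0618 without Nex_Ctrl replicate 1, Nex_Ctrl replicate 3 and Nex_cKO replicate 1.

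**Figure D1:**
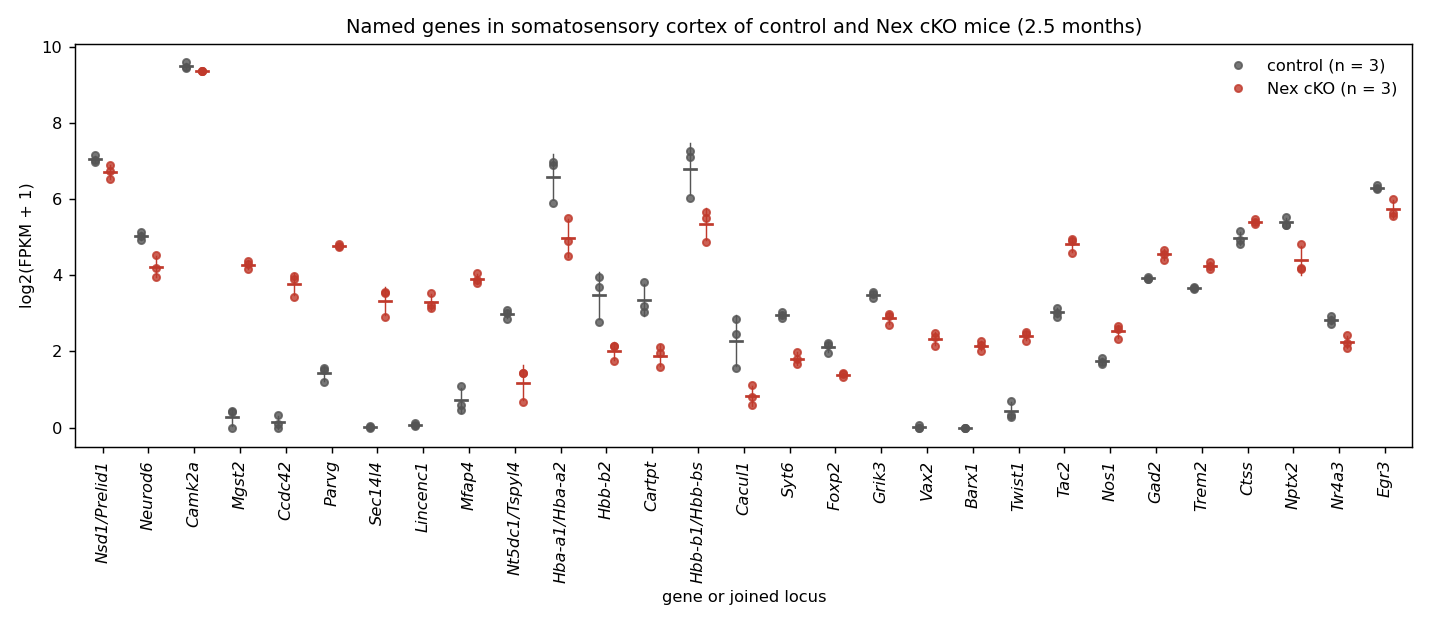
Expression of 29 named genes and joined loci in the Nex model as log2(FPKM + 1), one point per library (3 control, 3 cKO), with the group mean as a horizontal bar and the SD as a vertical line. Vax2, Barx1 and Twist1 lie near 0 in control libraries and at 3.45 to 4.36 FPKM on average in cKO libraries.

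Of 19 tested markers of layer 6 and subplate neurons, 7 fell and 0 rose (1 higher and 8 lower adjusted over the list alone), with a median log2 change of -0.32. Without Nex_cKO replicate 3, 1 rose and 7 fell of 21. Syt6, a synaptotagmin, fell from 6.77 to 2.53 FPKM (log2 change -1.14, SE 0.11, adjusted p = 0.000299). Foxp2, a transcription factor of layer 6 neurons, fell from 3.34 to 1.62 FPKM, and Grik3, a kainate receptor subunit, from 10.3 to 6.36 FPKM. Tbr1, a transcription factor that specifies layer 6 neurons, fell from 65.8 to 47.6 FPKM (log2 change -0.46, adjusted p = 0.00333, chosen after its values were seen). The list had camera adjusted p = 0.0024, and adjusted p = 0.524 with an estimated correlation. Of 20 layer 5 markers, 6 fell and 0 rose (2 higher and 8 lower adjusted over the list alone), with a median of -0.27. For the list fry gave adjusted p = 0.0613. Camera gave adjusted p = 0.0333, and adjusted p = 0.576 with an estimated correlation. The calls of single layer 5 markers hang on each library: 0, 0, 0, 2, 4 and 4 fell without Nex_Ctrl replicates 1, 2 and 3 and Nex_cKO replicates 1, 2 and 3 in turn, and 2 rose without Nex_cKO replicate 2. With no filter on low values 2 fell. The layer 5 list had adjusted p = 0.0587 without Nex_Ctrl replicate 2, 0.0673 without Nex_cKO replicate 2 and 0.05 with no filter on low values.

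Of 24 upper-layer markers, 3 rose and 3 fell (4 and 6 adjusted over the list alone). Wfs1, which encodes wolframin, rose from 19.08 to 52.98 FPKM, and Lamp5 fell from 178.5 to 109.0 FPKM, both chosen after their values were seen. As a list they had camera adjusted p = 0.911. Without Nex_Ctrl replicate 3 the upper-layer markers that fell numbered 2, and without Nex_cKO replicate 3 they numbered 5. Of 28 genes that pattern cortical areas, 2 rose and 8 fell (3 and 11 adjusted over the list alone). The list missed the camera threshold (adjusted p = 0.0508), and fry gave adjusted p = 0.0393. It passed in 7 other settings, with adjusted p = 0.0429, 0.0456 and 0.0218 without Nex_Ctrl replicate 1, Nex_Ctrl replicate 3 and Nex_cKO replicate 3, 0.0496 with a pseudocount of 0.1, 0.0483 with no filter on low values, 0.0355 with median ratio rescaling and 0.0176 with the length correction. Its lower members numbered 6, 3, 2, 4, 5 and 8 without Nex_Ctrl replicates 1, 2 and 3 and Nex_cKO replicates 1, 2 and 3 in turn, and 3 rose without Nex_cKO replicate 2. Of 23 genes of glutamatergic neurons in general, 1 rose and 3 fell (1 and 7 adjusted over the list alone; camera adjusted p = 0.122). In the same order of libraries left out, 0, 0, 0, 0, 0 and 1 of them rose and 2, 2, 2, 2, 5 and 4 fell. The 3 that fell with all libraries were Neurod6, the locus of the Cre insertion, Rtn4r and Tbr1. Tbr1 is also in the layer 6 and area patterning lists. Of the 28 area patterning genes, 11 are in another list too, so these lists are not separate results.

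Of 15 tested transcription factors of early patterning or of other tissues, 5 rose and 0 fell (5 higher and 1 lower adjusted over the list alone). The filter favours rises here, since a factor silent in control libraries enters the test only if it reaches FPKM 1 in cKO libraries. With no filter on low values 11 rose and 1 fell of 108, and the list was not called (adjusted p = 0.128). Vax2, a homeobox factor of the ventral forebrain and eye, was listed at 0 in 2 control libraries and at 0.0487 FPKM in the other, and had 3.45 to 4.57 FPKM in cKO libraries (adjusted p = 1.42e-05). Barx1, a homeobox factor of the developing stomach and teeth, was listed at 0 in all 3 control libraries and had 3.05 to 3.80 FPKM in cKO libraries (adjusted p = 1.42e-05). Twist1, a factor of mesenchymal tissue, rose from 0.372 to 4.36 FPKM (adjusted p = 6.8e-05). Pax2 and Tbx1 were the other members that rose. The median log2 change of the list was -0.02, opposite in sign to its mean of 0.51 and to the camera test (adjusted p = 0.0115), which was up, and adjusted p = 0.539 with an estimated correlation. With quantile normalization the list had adjusted p = 0.184.

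Of 35 markers of GABAergic neurons, 4 rose and 0 fell (the same counts adjusted over the list alone), with a median log2 change of 0.08. Of the 35, 21 had a positive and 14 a negative change. Without Nex_cKO replicate 2, 4 rose and 2 fell. Tac2, the precursor of neurokinin B, rose from 7.15 to 27.4 FPKM (log2 change 1.80, SE 0.11, adjusted p = 2.82e-05). Nos1, neuronal nitric oxide synthase, rose from 2.35 to 4.78 FPKM, and Gad2, which makes GABA, from 14.2 to 22.5 FPKM (adjusted p = 0.0035 and 0.00203). For this list fry gave adjusted p = 0.143. Camera gave adjusted p = 0.0115, and adjusted p = 0.576 with an estimated correlation. Without Nex_cKO replicate 2 the list had adjusted p = 0.078.

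Of 33 immediate early genes, which are induced by neuronal activity, 3 fell and 0 rose (the same counts adjusted over the list alone), with a median of -0.31. The number that fell was 1, 2, 3, 1, 5 and 11 without Nex_Ctrl replicates 1, 2 and 3 and Nex_cKO replicates 1, 2 and 3 in turn, and 1 rose without Nex_cKO replicate 2. Nptx2, a synaptic pentraxin, fell from 41.15 to 20.54 FPKM (SE of the log2 change 0.17, adjusted p = 0.00688). Nr4a3 fell from 6.09 to 3.78 FPKM and Egr3 from 78.2 to 52.8 FPKM (adjusted p = 0.0152 for both). Nr4a3 had adjusted p = 0.0623, 0.0738 and 0.0603 without Nex_Ctrl replicate 1, Nex_Ctrl replicate 3 and Nex_cKO replicate 1. Egr3 had 0.0644, 0.066, 0.0519 and 0.0673 without Nex_Ctrl replicates 1, 2 and 3 and Nex_cKO replicate 1. For the list fry gave adjusted p = 0.329. Camera gave adjusted p = 0.0249, and adjusted p = 0.739 with an estimated correlation. The list had adjusted p = 0.124, 0.198 and 0.173 without Nex_Ctrl replicate 1, Nex_cKO replicate 1 and Nex_cKO replicate 2, and 0.0573 with a filter of FPKM 5.

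Markers of other cell types moved in different directions. Of 21 microglial markers, 2 rose and 0 fell (the same counts adjusted over the list alone): the surface receptor Trem2 from 11.7 to 18.1 FPKM (adjusted p = 0.00205) and the protease cathepsin S, Ctss, from 30.4 to 41.6 FPKM (adjusted p = 0.024). Ctss had adjusted p = 0.0897, 0.0996 and 0.0957 without Nex_Ctrl replicate 2, Nex_Ctrl replicate 3 and Nex_cKO replicate 1. Fry gave adjusted p = 0.349 for the list. Camera gave adjusted p = 0.0115 for the list, and adjusted p = 0.72 with an estimated correlation. It was 0.131 without Nex_Ctrl replicate 2 and 0.113 without Nex_cKO replicate 1. The microglial markers that rose numbered 2, 1, 1, 1, 3 and 2 without Nex_Ctrl replicates 1, 2 and 3 and Nex_cKO replicates 1, 2 and 3 in turn. Of 22 endothelial markers, 2 fell and 0 rose (4 lower adjusted over the list alone): Egfl7 from 23.4 to 12.4 FPKM (adjusted p = 0.00689) and the tight junction protein claudin 5, Cldn5, from 39.9 to 25.5 FPKM (adjusted p = 0.0391). Cldn5 had adjusted p = 0.144, 0.134, 0.0724 and 0.0553 without Nex_Ctrl replicate 1, Nex_Ctrl replicate 3, Nex_cKO replicate 1 and Nex_cKO replicate 3. Endothelial markers as a list had camera adjusted p = 0.0115, and adjusted p = 0.626 with an estimated correlation. Fry gave adjusted p = 0.0807. In the same order of libraries left out, 1, 3, 1, 1, 4 and 1 endothelial markers fell. Of 24 oligodendrocyte markers, Fa2h, a fatty acid hydroxylase of myelin lipids, fell from 15.5 to 11.1 FPKM (adjusted p = 0.0115) and 22 had a negative change (4 lower adjusted over the list alone). Fa2h had adjusted p = 0.0607 and 0.0615 without Nex_Ctrl replicates 1 and 3. In the same order 0, 2, 0, 1, 3 and 2 oligodendrocyte markers fell. Oligodendrocyte markers as a list had camera adjusted p = 0.00305, and adjusted p = 0.576 with an estimated correlation. Fry gave adjusted p = 0.0564.

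Of 13 markers of reactive astrocytes, 2 rose and 1 fell (4 and 1 adjusted over the list alone). The intermediate filament Gfap rose from 25.9 to 45.9 FPKM and the protease inhibitor Serpina3n from 4.57 to 15.5 FPKM, while the heat shock protein Hspb1 fell from 9.86 to 3.77 FPKM, all chosen after their values were seen. Hspb1 had adjusted p = 0.0357 with all libraries, and 0.135, 0.13, 0.0603 and 0.0586 without Nex_Ctrl replicate 1, Nex_Ctrl replicate 3, Nex_cKO replicate 1 and Nex_cKO replicate 3. Camera gave adjusted p = 0.0259 for the list, and adjusted p = 0.547 with an estimated correlation. It was 0.0692 without Nex_Ctrl replicate 2, 0.0609 without Nex_cKO replicate 3, 0.184 with quantile normalization, 0.0504 with the length correction and 0.247 (median log2 change 0.03) with no filter on low values. Of 14 hippocampal markers, 4 rose and 2 fell (5 and 2 adjusted over the list alone). Cpne7, a calcium-binding copine, rose from 4.77 to 13.1 FPKM (chosen after its values were seen). These markers as a list had camera adjusted p = 0.0289, and adjusted p = 0.547 with an estimated correlation. It was 0.0676 without Nex_cKO replicate 1, 0.0701 without Nex_cKO replicate 3, 0.319 with quantile normalization, 0.122 with no filter on low values, 0.149 with a filter of FPKM 5, 0.0581 with median ratio rescaling and 0.0646 with the length correction. The hippocampal markers that fell numbered 1, 1, 0, 0, 2 and 2 without Nex_Ctrl replicates 1, 2 and 3 and Nex_cKO replicates 1, 2 and 3 in turn.

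Genes of ribosomal proteins and of oxidative phosphorylation had small shared differences. Of 69 ribosomal protein genes, 60 had a negative change, with a median log2 change of -0.20, and 1 passed the test (0 adjusted over the list alone). That gene, Rps20, fell from 381.1 to 279.9 FPKM (adjusted p = 0.0416). Rps20 had adjusted p = 0.152, 0.0553, 0.171 and 0.149 without Nex_Ctrl replicates 1, 2 and 3 and Nex_cKO replicate 1. The ribosomal genes that fell numbered 0 without each of these 4 libraries, 12 without Nex_cKO replicate 2 and 1 without Nex_cKO replicate 3. Of 71 oxidative phosphorylation genes, 64 had a negative change, with a median of -0.16, and none passed limma's test over all genes (0 over the list alone). Without Nex_cKO replicate 2, 4 of them fell, and without Nex_cKO replicate 3, 1 fell. Fry gave the lists adjusted p = 0.277 and 0.365. By camera they had adjusted p = 0.0024 and 0.00373, and adjusted p = 0.739 and 0.752 with an estimated correlation. Both had adjusted p = 0.37 with quantile normalization. Without Nex_cKO replicate 3, the library in which long genes had the highest values relative to short ones, they had adjusted p = 0.0807 and 0.34.

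**Figure D2:**
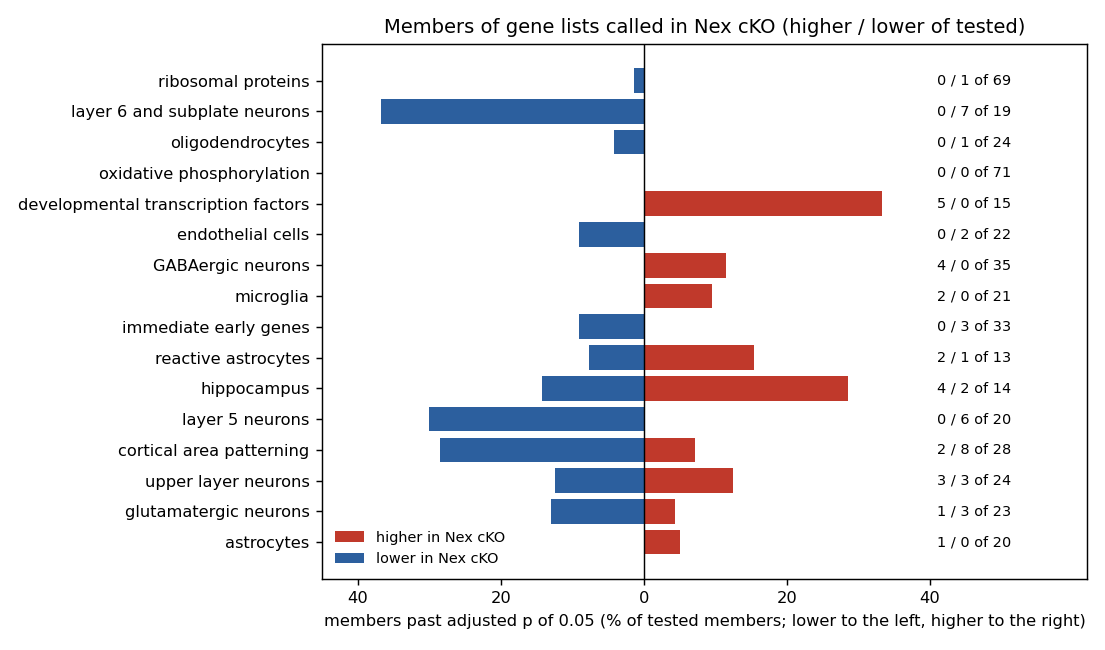
Share of the tested members of 16 gene lists that were higher (right) or lower (left) in Nex cKO at adjusted p under 0.05, in percent, with counts at the right. The lists are the 12 past the camera threshold and 4 others for comparison. Of the 12, 0 pass with an estimated correlation, a test with few residual degrees of freedom. Markers of layer 6 and subplate (0 higher, 7 lower of 19) and layer 5 (0 higher, 6 lower of 20) had more lower than higher members. Developmental transcription factors had 5 higher of 15, and 11 higher and 1 lower of 108 with no filter on low values.

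The second comparison asks what changes when Nsd1 is deleted later, in the Camk2a model. No gene passed the test, so single genes are given as values. Nsd1 (ENSMUSG00000021488, chromosome 13, 55209782 to 55318325) had 5.61 and 8.87 FPKM in the control libraries and 4.31 and 4.99 FPKM in the cKO libraries (log2 change -0.52, SE 0.20, limma adjusted p = 0.685). Its neighbour Prelid1 had 34.8 and 35.3 FPKM against 32.5 and 33.0 FPKM. Neurod6 had 24.0 and 24.4 FPKM against 24.3 and 13.9 FPKM, and its change was 0.0072 without Camk2a_cKO replicate 2. Camk2a had 497.2 and 551.8 FPKM against 530.0 and 574.3 FPKM, and the sign of its difference changed without Camk2a_Ctrl replicate 1 (log2 change -0.0002).

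Of 12919 genes tested with limma, 0 were higher and 0 lower at adjusted p under 0.05. At an unadjusted p under 0.05, 466 genes had a positive and 433 a negative change. These are 899 in all, where chance gives 646. The other tool run, limma voom on the recovered reads, called 1 gene: Asb2, a subunit of a ubiquitin ligase known from muscle and blood, at a log2 change of 2.21 (adjusted p = 0.0466). Asb2 had 0.904 ± 0.0949 FPKM in controls and 4.22 ± 0.182 FPKM in cKO libraries (SD, n = 2 each), with adjusted p = 0.158 in limma on log2(FPKM + 1). The other genes of smallest p with positive changes were Gm5805, a processed pseudogene (8.57 and 25.1 FPKM on average, adjusted p = 0.0632), and the microRNA genes Gm22121 and Mir7231, both listed at 0 in control libraries. Gm5805 had adjusted p = 0.0158 with a filter of FPKM 5 and 0.0424 with robust variance moderation. Without the intensity trend 5 genes passed, each at adjusted p = 0.04998: Asb2, Gm5805, Gm23873, Mir343 and Mir7231. The genes of smallest p with negative changes were the processed pseudogene Gm14303 (112.4 and 55.3 FPKM on average), the small nuclear RNA Gm25596, the small nucleolar RNA Gm25108 and the microRNA gene Mir7669, each at adjusted p = 0.318.

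By camera, 7 lists moved in the Camk2a model, with no single member past the threshold over all genes. Fry called 0 lists (lowest adjusted p = 0.416). The shift of a list can hang on a single library here. Oxidative phosphorylation genes, not called with all libraries (median log2 change 0.022), had medians of opposite sign. These were -0.095 without Camk2a_cKO replicate 1 and 0.155 without Camk2a_cKO replicate 2. Mitochondrially encoded genes had a negative change in all 13 members (median log2 change -0.36; adjusted p = 7.59e-09, and adjusted p = 0.838 with an estimated correlation). This list had a median of 0 and adjusted p = 0.226 with quantile normalization, under which the highest genes are set to equal values. In it, mt-Nd1 had 8566 and mt-Nd2 5052 FPKM in controls against 6673 and 3901 FPKM. Of 80 ribosomal protein genes, 68 had a negative change (median -0.13; adjusted p = 7.59e-09, and adjusted p = 0.862 with an estimated correlation), with Rps12 at 23.3 against 16.9 FPKM and Rpl26 at 123.3 against 96.1 FPKM. No member of either list passed adjusted over the list alone.

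Layer 5 markers had a negative change in 16 of 19 (median -0.12; adjusted p = 0.00107, and adjusted p = 0.838 with an estimated correlation), with 3 lower adjusted over the list alone. The transcriptional regulator Ldb2 had 10.1 against 6.08 FPKM, and Trib2 had 14.1 against 9.26 FPKM. Immediate early genes had a negative change in 24 of 35 (median -0.19; adjusted p = 0.00107, and adjusted p = 0.838 with an estimated correlation), with 1 higher and 4 lower adjusted over the list alone. Arc, an activity-induced regulator of synapses, had 150.4 against 93.2 FPKM, and Gadd45b had 4.28 against 6.99 FPKM. Genes of cortical area patterning had a negative change in 22 of 29 (median -0.12; adjusted p = 0.0031), and markers of layer 6 and subplate in 13 of 18 (median -0.09; adjusted p = 0.0356), with none past the threshold over the list alone. Both had adjusted p = 0.838 with an estimated correlation. Lmo4 had 48.0 against 34.1 FPKM, Lmo3 19.7 against 15.3 FPKM and Nr4a2 14.9 against 10.9 FPKM. Genes of red blood cells had a positive change in 7 of 8 (median 0.42; adjusted p = 0.00107, and adjusted p = 0.838 with an estimated correlation), with 2 higher adjusted over the list alone, Hbb-bs (43.6 and 75.0 FPKM) and Hba-a1 (34.0 and 48.9 FPKM). Without Camk2a_cKO replicate 1, adjusted p was 0.508 for immediate early genes and 0.13 for area patterning, for layer 6 and for red blood cells. Layer 6 and subplate markers had adjusted p = 0.19 without Camk2a_Ctrl replicate 2 and 0.0532 with the replicate block. Developmental transcription factors missed the threshold (8 of 9 positive, adjusted p = 0.0504), and had adjusted p = 0.0492 with a pseudocount of 0.1, 0.038 without the intensity trend and 0.0104 without Camk2a_Ctrl replicate 2, with Barx2 at 2.75 against 4.46 FPKM and Foxc1 at 1.05 against 1.73 FPKM.

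The difference between the changes was tested on 10407 genes, and 55 differed between the models. The change was more positive in the Nex model at 39 of them and more negative at 16. This balance turned without Nex_cKO replicate 2 (44 more positive, 48 more negative) and without Camk2a_cKO replicate 1 (29 and 36). Card10, a scaffold of NF-kappaB signalling, rose from 0.659 to 11.1 FPKM in Nex cKO and had 0.976 against 1.16 FPKM in the Camk2a model (difference of log2 changes 2.76, SE 0.23, limma adjusted p = 0.000823). Mfap4 (difference 2.37), the carboxylesterase gene Ces5a (2.15) and Fam114a1 (1.94) also had the more positive change in the Nex model. Kcnip2, a potassium channel subunit, fell from 90.8 to 47.1 FPKM in Nex cKO and had 38.2 against 47.8 FPKM in the Camk2a model (difference -1.25, SE 0.17, adjusted p = 0.00651). Dlk2, a Notch ligand homologue, had a difference of -1.21, Cldn5 of -1.20 (adjusted p = 0.0407) and the trafficking protein Trappc6a of -1.04 (adjusted p = 0.0407). The number of differing genes was 28, 25 and 31 without Nex_Ctrl replicates 1, 2 and 3, 27 and 92 without Nex_cKO replicates 1 and 2, and 15 without Camk2a_Ctrl replicate 1. Kcnip2 had adjusted p = 0.0665 without Camk2a_Ctrl replicate 1, and Ces5a had 0.0541 with a pseudocount of 0.1. Cldn5 had adjusted p = 0.103, 0.107 and 0.0797 without Nex_Ctrl replicate 1, Nex_Ctrl replicate 3 and Nex_cKO replicate 1. It had 0.18, 0.0962, 0.097 and 0.07 without Camk2a_Ctrl replicates 1 and 2 and Camk2a_cKO replicates 1 and 2. Trappc6a had 0.11, 0.102, 0.101 and 0.0564 without Nex_Ctrl replicates 1 and 2 and Nex_cKO replicates 1 and 3. It had 0.201, 0.0928 and 0.0687 without Camk2a_Ctrl replicate 1 and Camk2a_cKO replicates 1 and 2.

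The overlap asks whether the models share genes. No gene was called in both, since limma called 0 in the Camk2a model. At an unadjusted p under 0.01 in each, 36 genes were higher in both where chance gives 2.43 (odds ratio 32.1, Fisher's exact p = 2.19e-34), and 24 were lower in both where chance gives 4.30 (odds ratio 8.65, p = 9e-13). With no filter on low values 39 were higher in both where chance gives 4.62 (Fisher's exact p = 2.22e-27) and 15 lower where chance gives 2.84 (p = 7.89e-08). Genes are not independent replicates. Parvg had 1.39 against 5.49 FPKM in the Camk2a model, Asb2 rose from 1.47 to 11.2 FPKM in Nex cKO, and Nhlh1, a factor of newborn neurons, rose from 0.476 to 6.36 FPKM in Nex cKO and had 0.206 against 2.63 FPKM in the Camk2a model. Cartpt had 4.51 against 2.06 FPKM in the Camk2a model. These 4 examples were chosen after their values in both models were seen. Across the 10407 genes, the log2 changes of the models had Pearson's r = 0.229 and Spearman's rho = 0.012.

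**Figure D3:**
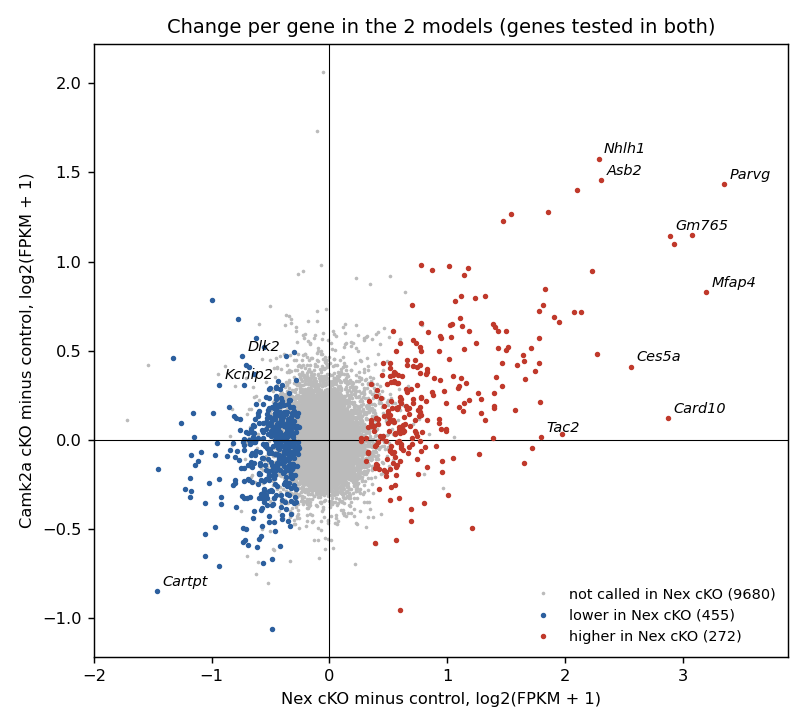
Log2 change (cKO minus control, log2(FPKM + 1)) of 10407 genes in the Nex model (x) and the Camk2a model (y), one point per gene. Of the 560 genes higher in Nex cKO, 272 were tested in both models (red) and 209 of these lie above 0 in the Camk2a model. Of the 509 lower genes, 455 were tested in both (blue) and 279 lie below 0.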

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

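The counts over other splits of the samples were planned before the data were examined. The tests of the gene length trend, of Nex_cKO replicate 3, of other cell types and of the Nex genes in the Camk2a model were chosen after the results were seen.

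A test of the difference itself flagged 55 genes whose change differed between the Nex and the Camk2a model. Among named genes, the log2 change in Nex cKO minus that in Camk2a cKO was 2.76 for Card10, 2.37 for Mfap4, 2.15 for Ces5a, 1.94 for Fam114a1, 1.92 for Parvg and 1.78 for Tac2. It was -1.25 for Kcnip2, -1.21 for Dlk2, -1.20 for Cldn5 and -1.04 for Trappc6a. Leaving out single libraries gave 28, 25 and 31 differing genes (Nex_Ctrl replicates 1, 2 and 3), 27 and 92 (Nex_cKO replicates 1 and 2) and 15 (Camk2a_Ctrl replicate 1). The change was more positive in the Nex model at 39 and more negative at 16, which turned to 44 and 48 without Nex_cKO replicate 2 and to 29 and 36 without Camk2a_cKO replicate 1. Age, driver, sex of most libraries and table differ together between the models, so what in them underlies a difference cannot be read from these data. Rows without a gene name, which no comparison used, held 41.55% of the summed FPKM of Nex_cKO replicate 3, above the 2.33% to 19.4% of the 3 control libraries.

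The first pattern weighed is the rise of 560 genes in Nex cKO, many from near 0. Of the 10 splits of the 6 libraries into 3 and 3, 1 (the real one) gave as many higher genes and 1 as many lower genes (560 and 509, with a highest other count of 0), and 10 splits are too few for a share under 0.05. Removing each library's trend with gene length kept 99.4% of the higher genes that have a length (514 of 517), and leaving out Nex_cKO replicate 3 kept 92.3% of all (517 of 560), which argues against either as the whole cause. The highest median log2 change over 15 lists of other cells, ages and regions was 0.164 (reactive astrocytes, SD 0.628 over members that went both ways). Immature neurons (median 0.001, SD 0.632) and hippocampus (0.072, SD 0.573) also spread widely. More RNA of these cells, or of cells without a list, cannot be told from a rise within neurons. Medians were -0.01 (SD 0.193) for astrocytes, 0.129 (SD 0.193) for microglia, -0.17 (SD 0.22) for endothelial cells and -0.183 (SD 0.166) for oligodendrocytes. The first quartile of the higher genes was 0.627, which argues against more RNA of those cells as the whole cause. Of the genes higher in Nex cKO, 230 had a control mean of FPKM 1 or more in the Camk2a model. There these 230 had a median log2 change of 0.1491. Random lists matched on control expression gave -0.0256 to 0.0219. All 517 genes higher in Nex cKO that the Camk2a table holds had 0.1748 against -0.0115 to 0.0116. Those random lists were drawn from every row, also rows at 0 in all libraries, which pulls their range to 0. Among the 272 past the filter camera gave p = 0.0382 with an estimated correlation and fry p = 0.0519. The values of the 230 genes are what loss of NSD1 raising some of them under either driver would give. Differences in strain, litter or handling that follow the genotype stay untested.

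The second pattern weighed is the small shared negative change of ribosomal protein and oxidative phosphorylation genes in Nex cKO, with median log2 changes of -0.20 and -0.16. As single genes, 1 of 69 and 0 of 71 passed the test. Without Nex_cKO replicate 3 the medians were -0.071 and -0.037 and neither list was called (adjusted p = 0.0807 and 0.34), so much of the pattern may come from that library, the one with Y-linked transcripts among the Nex samples and the one with a strong trend with gene length. The longest eighth of genes lay 0.285 above the shortest in it, against -0.105 to 0.008 in the other 5. With that trend removed the medians were -0.107 and -0.066 and both lists stayed called by camera with the preset correlation. The ribosomal median kept over 50% of its size, a bound chosen after the results were seen, and that of oxidative phosphorylation lost over 50%. The estimated correlations of the lists were 0.488 and 0.699. Their calls with the preset 0.01 therefore cannot weigh against the trend, which stays open for both. With an estimated correlation neither list was called in the main test (camera adjusted p = 0.739 and 0.752). Sex and an effect of Nsd1 deletion stay open, and no biological explanation was tested.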

How the results depend on the processing

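The length correction, voom on recovered reads, the gene lists under further settings and without single libraries, and joint settings of the overlap were chosen after seeing the data; the other settings were planned. All 1069 genes called in Nex cKO kept their sign under each of the 15 alternatives wherever they were tested. Only quantile normalization, median ratio rescaling and the length correction could have changed a sign. At each of these genes the cKO values lay on one side of the control values, which fixes the sign under the other settings. The number of higher genes stayed within 1.5 times 560 except with a filter of FPKM 5 (197, of fewer genes tested). The number of lower genes was 298 with median ratio rescaling, which moved the median of all genes from -0.0431 to 0.0056, and 160 to 685 without single libraries. In the Camk2a model the count of higher genes, 0, became 1 with a filter of FPKM 5, 5 without the intensity trend, 1 with robust variance moderation and 1 with voom on recovered reads, and no setting called a lower gene. The 55 genes that differed between the models became 32 with a pseudocount of 0.1, 276 with no filter on low values and 15 to 92 without single libraries. The overlap, 0 in the main test, was 36 higher and 24 lower genes at an unadjusted p under 0.01, and 1 higher gene with voom. Of the 12 lists called in Nex cKO, 0 held with an estimated correlation and fry called 7 lists, 4 of them among these. These 4 were layer 6 and subplate, developmental transcription factors, hippocampus and reactive astrocytes. Fry called none of the others among the 12. A loss with an estimated correlation does not by itself show correlated members, since that test has few residual degrees of freedom. Layer 6 and subplate markers lost their call in Nex cKO with an estimated correlation of -0.0135, below the preset 0.01. Other lists had high estimates. In Nex cKO these were 0.488 for ribosomal proteins, 0.699 for oxidative phosphorylation, 0.377 for microglia and 0.369 for immediate early genes. In Camk2a cKO they were 0.561 for mitochondrially encoded genes and 0.290 for ribosomal proteins. For such lists the preset 0.01 can make the camera p-values far too small. Of 7 lists called in Camk2a cKO, 0 held with an estimated correlation and fry called 0. Without Camk2a_Ctrl replicates 1 and 2 and Camk2a_cKO replicates 1 and 2 in turn, 9, 8, 5 and 16 lists were called, of which 7, 6, 3 and 7 are among these, and the replicate block ended the call of layer 6 and subplate markers. Fewer samples or genes tested apart, the cause was not tested.

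The replicate block gave 272 lower genes in Nex cKO, where 509 were called without it, and 29 genes that differed between the models. The numbers do not pair the Nex libraries: deviations from the group means correlated across genes at 0.017, -0.104 and -0.096 between libraries of the same number, and at -0.075 to 0.134 between others.

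Of 33 named genes in the Nex model, 21 kept direction and side of the threshold under all settings, 10 lost a call in at least 1, 1 gained one and 1 changed sign: Camk2a, at 0.0039 with quantile normalization. Of 26 in the Camk2a model, 19 kept both, 3 gained a call, 2 (mt-Nd1 and mt-Nd2) had a change of 0 with quantile normalization and 2 changed sign without a single library: Neurod6 (-0.7605 to 0.0072) and Camk2a (-0.0002 to 0.1499), neither past the threshold. Of 8 named differences, 4 kept their call and 4 lost it in at least 1 setting. Developmental transcription factors had too few members to be tested in Nex cKO with a filter of FPKM 5. A test with edgeR was planned for raw counts and not run, since the tables hold FPKM. The reads recovered for the Camk2a model were fitted with voom instead. The unknown depth of the Nex libraries limits what can be said of genes listed at 0.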

Other observations

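The test of Neurod6 was chosen after its result was seen, as were both narrower counts of neighbouring genes. The tests of strain segments and of adjacent pairs of all higher genes were written down before their results were seen. The genes named in the next paragraph were chosen after their values were seen.

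Neuropeptide genes moved both ways in Nex cKO: of 25 tested, 4 rose and 1 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.195). Without Nex_cKO replicate 2, 4 rose and 7 fell, and without Nex_cKO replicate 3 the list was called upward (adjusted p = 0.0218). Adcyap1, the precursor of the peptide PACAP, rose from 5.08 to 13.1 FPKM and Pdyn, the precursor of dynorphins, from 9.25 to 15.2 FPKM. Adcyap1 had 5.70 against 3.75 FPKM in the Camk2a model, and its change differed between the models by 1.71 on the log2 scale (SE 0.17, limma adjusted p = 0.0016). Of 59 potassium channel genes, 3 rose and 11 fell (4 and 17 adjusted over the list alone). The list missed the camera threshold (adjusted p = 0.0799), and fry gave adjusted p = 0.0393. It passed without Nex_Ctrl replicate 1 (adjusted p = 0.0466), with no filter on low values (0.0483), with median ratio rescaling (0.0496) and with the length correction (0.0212). Its lower members numbered 4, 3, 2, 3, 14 and 12 and its higher ones 1, 1, 2, 1, 2 and 3 without Nex_Ctrl replicates 1, 2 and 3 and Nex_cKO replicates 1, 2 and 3 in turn. Kcng1 fell from 4.35 to 1.58 FPKM and Kcnj6 from 14.5 to 10.6 FPKM. Mylk, a kinase of smooth muscle contraction, rose from 3.80 to 14.1 FPKM. Of 15 markers of mural cells, the list that holds Mylk, 3 rose and 0 fell (3 and 1 adjusted over the list alone). In the same order of libraries left out, 1, 1, 1, 2, 2 and 3 rose. Without Nex_cKO replicate 3, 1 fell. The list was not called (median log2 change -0.003, camera adjusted p = 0.207).

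Genes lower in Nex cKO had, in the Camk2a model, a median log2 change of -0.0479 over 455 genes, where random lists matched on expression gave -0.0325 to -0.0032 (camera p = 0.00107, p = 0.263 with an estimated correlation, fry p = 0.173). Among genes chosen by their control mean alone it was -0.0516 against -0.0382 to -0.008.

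Neurod6 carries the Cre insertion of the Nex driver, which may by itself lower its transcript in Nex cKO if the controls lack Cre. The insertion predicts a change that differs from that in the Camk2a model. The log2 change was -0.80 in the Nex model and -0.38 in the Camk2a model, and the difference had adjusted p = 0.5467. With the Cre status of the controls unstated and Neurod6 at 24.3 and 13.9 FPKM in the Camk2a_cKO libraries, an insertion effect and an effect of Nsd1 deletion cannot be told apart for this gene.

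Segments of another strain around the modified loci could bring called genes near Nsd1 or Neurod6. Within 10 Mb of either, 17 of 176 tested genes were called (9.7%), against 8.6% elsewhere, an odds ratio of 1.137 (95% interval 0.644 to 1.89, Fisher's exact p = 0.588). The upper limit lies under 2, which argues against such segments as a source of many calls.

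A hypothesis was that higher genes lie side by side on the chromosomes, as they might if loss of NSD1 acted on whole domains. Of the 517 higher genes with a position, 48 adjacent pairs were both higher, where 10000 permutations of the calls among tested genes gave 15 to 32 in their middle 95% (permutation p = 1e-04, the smallest they can give). Examples are Mfng and Card10, and Pik3r6 and Ccdc42. With pairs at least 5 kb apart and of different family names, there were 32 against 9 to 24 (permutation p = 4e-04), and 32 against 10 to 25 when calls were permuted within 10 bins of mean expression (permutation p = 0.0007). Lower genes formed 23 adjacent pairs against 11 to 28 (permutation p = 0.235). The filter bears on the pairs of higher genes. Of all 560 higher genes, 252 had a control mean under FPKM 1 and entered the test only through a rise. Silent neighbours that did not rise were not tested and are skipped when pairs are formed. The permutations do not allow for this, so the excess of pairs cannot be told from an effect of the filter. The data hold no histone marks, so whether such pairs share a domain was not tested.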
